A study of Rattus norvegicus with 30 samples.

How the data were processed

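The study measured gene expression in whole stomach, jejunum and colon of 30 female DA rats with Affymetrix rat genome arrays. Rats were killed 1, 6, 24 or 72 h after 1 intraperitoneal dose of irinotecan (200 mg/kg), and a group killed at 0 h got none. RNA was pooled from 3 rats and each of the 15 tissue and time groups had 2 such pools, so 30 arrays were used. Each time had 6 rats, so the 3 tissues of a time came from the same rats, and whether equal replicate numbers hold the same rats is not given in the sources used here. Whether the rats at 0 h had a sham injection or anaesthetic is not given in the sources used here. Tissue, time and replicate were taken from the sample titles.

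The values are log2 signals as deposited, made by the authors with RMA per the submitters' processing notes. The RMA version, and whether the 30 arrays were processed together, are not given in the sources used here. Values ran from 3.53 to 14.32, array medians from 6.965 to 7.055, and replicate correlations over probe sets from 0.9469 to 0.9959, so no further scaling was applied. Image and probe-level files were not used here, so the normalization was not redone from them.

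Of 31099 probe sets 57 array controls were left out of the tests, which left 31042 to test. Of these 20826 carried 1 gene symbol (14217 genes), 436 several and 9780 none, and 20758 were matched by gene identifier to the current gene table, which changed 0 symbols. Probe sets with several symbols or none were tested and counted but not named. Gene lists were written as symbols, 42 lists with 734 entries of which 635 were measured. Of the 625 distinct genes measured 10 stood on more than 1 list. A gene of a list was represented by its brightest probe set.

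Within each tissue the 5 times were fitted together with limma 3.58.1 under R 4.3.3, each time was compared with 0 h and 72 h with 24 h, and p was adjusted by Benjamini-Hochberg over the 31042 probe sets with a threshold of 0.05. Tissue differences in each response were F tests of the interaction in 1 limma fit of all 30 arrays, which treats arrays of different tissues as independent although they share rats. Lists were compared with all other named genes by limma's camera with a preset correlation of 0.01 between genes, adjusted over 504 tests of 42 lists, 3 tissues and 4 times, and again with the correlation estimated from the arrays. camera is a two-sided test here and limma's adjusted p are two-sided. Each error printed is the standard error of the log2 fold change from limma, and each spread beside a mean is the standard deviation of 2 arrays. With 2 arrays against 2, chance alone keeps the groups of a gene from overlapping in 1 of 3 cases. Expected overlaps were computed from independent lists of the same sizes, and the effect of shared 0 h arrays was simulated.

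Genes were named by a rule: in each comparison with 0 h the 8 highest and 8 lowest changes among probe sets past the threshold whose treated and 0 h arrays did not overlap, with 1 symbol. Added to these were at most 4 members of each list past camera, and Cdkn1a, Mdm2, Ccng1, Fos, Per1, Ccnb1, Mcm5 and Ptgs2 where they are described. Where nothing passed, the 5 smallest p were eligible, and for 72 h against 24 h and for tissue differences the 5 smallest adjusted p. Other members of a list are named where their list is described, whether or not they passed. Not every gene the rule allows is named, to keep the text short.

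The comparisons, tests, lists, the naming rule and a first group of other settings were set before the data were examined. That group held dropping probe sets with a mean under the median, quantile normalization of the deposited values, limma with a trend and robust variances, 1 fit of all 30 arrays, a replicate block, leaving out each array of the compared groups, or of the tissue for lists, the other probe sets of a gene, and for lists the estimated correlation and the mean of all probe sets of a gene. Further settings had rules set after seeing which arrays stood out. These were array weights, leaving out arrays whose pancreatic acinar list median or Pgc lay over 2 log2 above the highest 0 h array of the tissue, and leaving out arrays whose GAPDH 3' signal lay over 0.5 log2 above its 5' signal.

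The limma tests were tested on simulated data with the arrays' own spread, 2 arrays against 2, and with noise independent between probe sets. The real arrays also differ by shifts that many genes share, which this simulation left out, so its rates may not hold for them. In the stomach at 1 h 60.6% of 2-fold changes and 91.3% of 4-fold changes were found with 6 false calls, and in the jejunum at 6 h 87.7% and 100% with 7. In the colon at 6 h 24.5% of 1.5-fold changes were found, against 57.1% in the jejunum. With a simulated correlation of 0.3 between genes, camera at the preset correlation called 39, 41 and 40 of 158 unshifted lists in stomach, jejunum and colon at 6 h, against 0, 0 and 1 for independent genes. With the estimated correlation it called 0 of these in each tissue and found 1 of 10 shifted lists in each, or 2, 8 and 8 for independent genes. The precision of a comparison is given by its median standard error.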

Results

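Stomach, jejunum and colon were compared 1, 6, 24 and 72 h after 1 dose of irinotecan with the same tissues of undosed rats (0 h), on 2 arrays per tissue and time, each carrying RNA pooled from 3 rats. Each tissue carried its own transcripts: Atp4a lay at 12.77 to 13.55 in the stomach and 6.66 to 7.12 in the jejunum, Apoa4 at 13.63 to 14.04 in the jejunum and 6.66 to 9.62 in the stomach and 6.67 to 10.31 in the colon, and Car1 at 11.99 to 13.44 in the colon and 6.19 to 6.69 in the jejunum. Pgc was 6.48 to 13.67 across the colon arrays, Gkn1 5.83 to 10.14, Aqp8 9.67 to 12.18, Slc26a3 12.04 to 12.69 and Fabp2 9.78 to 12.06, all in log2 units. Numbers in brackets after a gene are log2 fold changes against 0 h from 2 arrays against 2, with the standard error and limma's adjusted p for the first gene of a sentence. A gene list that camera placed past the threshold did so at a preset correlation between genes, and every such call was lost when the correlation was estimated from the arrays.

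**Figure D1:**
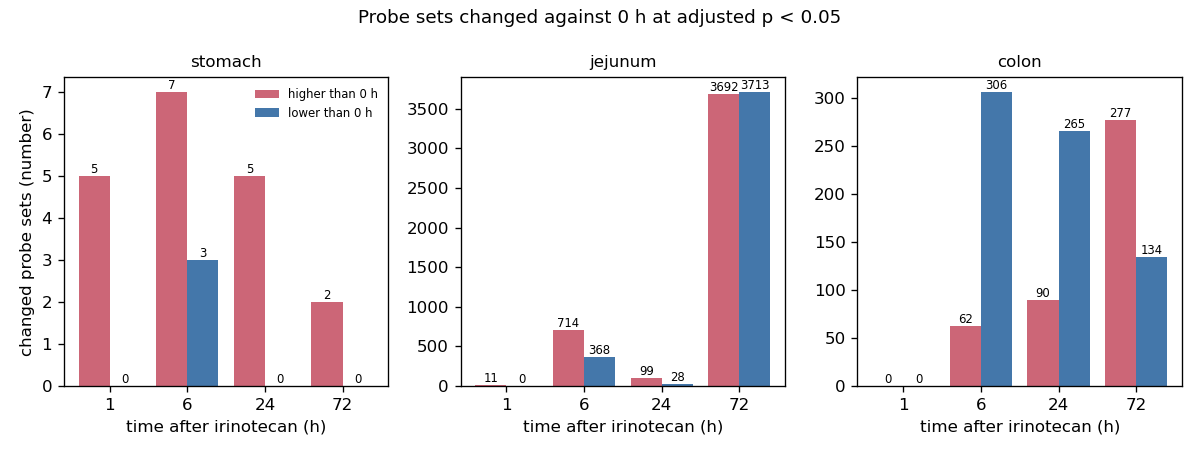
Number of probe sets higher or lower than at 0 h at adjusted p < 0.05 in each tissue and time, from 2 arrays against 2. Each panel has its own vertical scale. Jejunum at 72 h stood highest with 7405, while the stomach had at most 10.

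**Figure D2:**
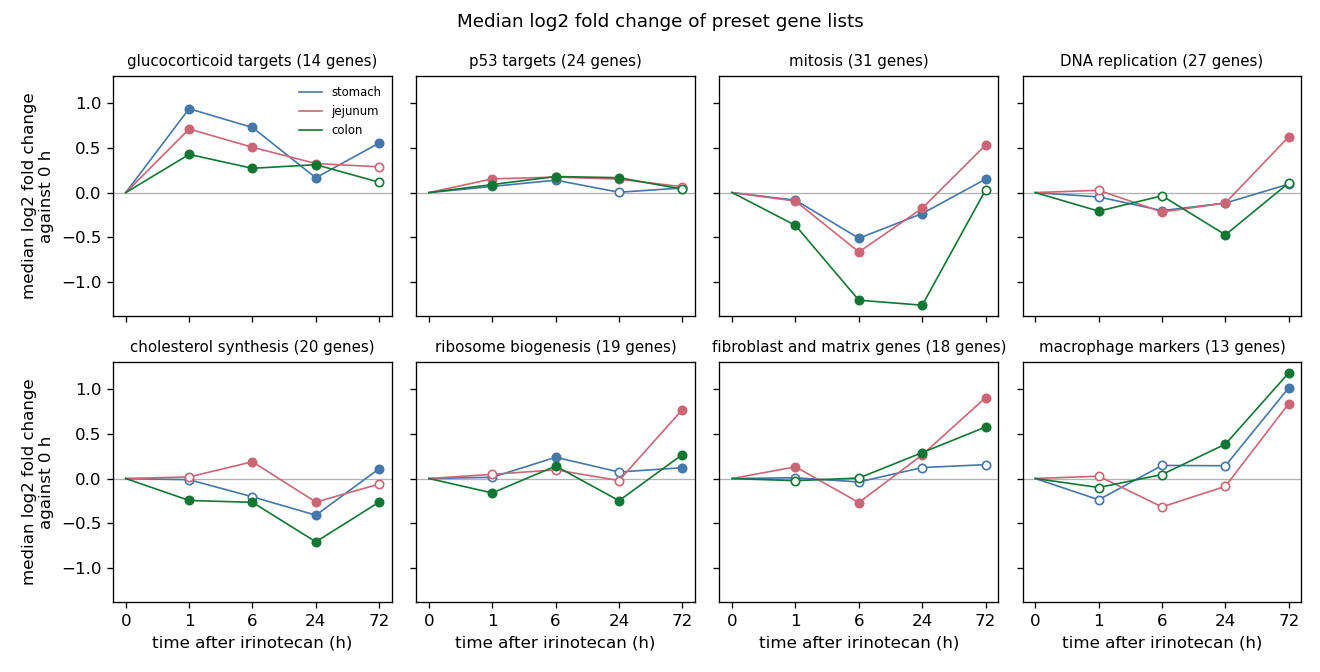
Median log2 fold change against 0 h of the measured genes of 8 preset lists. Filled points passed camera at the preset correlation and open points did not. The lowest points are mitosis in the colon at 24 h (-1.26) and 6 h (-1.21), and in the jejunum mitosis ran from -0.67 at 6 h to 0.53 at 72 h.

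In the stomach at 1 h, Chac1 (2.05 ± 0.17, adjusted p = 0.0343), Rhob (1.66), Nr4a1 (1.63) and Pim3 (1.41) rose. Chac1, which encodes a glutathione-degrading enzyme, went from 8.37 ± 0.14 at 0 h to 10.42 ± 0.21 at 1 h. Among the immediate early genes, 1 rose, or 13 when adjusted over the list alone (median 0.63). The immediate early list had camera adjusted p = 6.55e-20, and adjusted p = 0.275 with an estimated correlation. Zfp36 (1.58 ± 0.18, adjusted p = 0.0716) lay higher without passing. For the 14 glucocorticoid targets, 0 rose, or 8 when adjusted over the list alone (median 0.94). The glucocorticoid list had camera adjusted p = 1.9e-15, and adjusted p = 0.275 with an estimated correlation. Of these, Ddit4 (2.12 ± 0.25, adjusted p = 0.0738) and Tsc22d3 (0.89) came closest to passing. The p53 target Cdkn1a (1.19 ± 0.27, adjusted p = 0.54) and the clock gene Per1 (0.73) did not pass, nor did Fos (1.36). limma called 5 of 31042 probe sets, all higher, with 1776 at unadjusted p < 0.05 and a median standard error of 0.122. The count was 0 without 0 h replicate 1, 0 without 0 h replicate 2, 0 without 1 h replicate 1 and 0 without 1 h replicate 2.

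At 6 h the stomach carried more Mt2A (2.94 ± 0.21, adjusted p = 0.00659), Pdk4 (2.29), Angptl4 (1.89), Tmem252 (1.76) and Sphk1 (1.19), and less Slc8a1 (-1.31) and Mipol1 (-1.27). Another probe set of Slc8a1 differed by 0.12. Pdk4, whose product holds back pyruvate oxidation, stood at 8.92 ± 0.042 at 0 h and 11.20 ± 0.12 at 6 h. Pdk4 and Angptl4, an inhibitor of lipoprotein lipase, belong to the fatty acid oxidation list, of whose 18 genes 2 rose, or 6 when adjusted over the list alone (median 0.29). The fatty acid oxidation list had camera adjusted p = 0.000134, and adjusted p = 0.306 with an estimated correlation. Of the 31 mitosis genes 0 fell, or 16 when adjusted over the list alone (median -0.51). The mitosis list had camera adjusted p = 1.54e-14, and adjusted p = 0.667 with an estimated correlation. Ccnb1 itself did not pass (-0.78, adjusted p = 0.329). Of the immediate early genes 0 rose, or 14 when adjusted over the list alone (median 0.75). The immediate early list had camera adjusted p = 4.52e-14, and adjusted p = 0.306 with an estimated correlation. Of the glucocorticoid targets 1 rose, or 8 when adjusted over the list alone (median 0.73). The glucocorticoid list had camera adjusted p = 3.8e-11, and adjusted p = 0.275 with an estimated correlation. Endoplasmic reticulum stress genes shifted downwards, where 0 fell, or 6 when adjusted over the list alone (median -0.36). The endoplasmic reticulum stress list had camera adjusted p = 0.000166, and adjusted p = 0.586 with an estimated correlation. Hspa5 (-0.71 ± 0.12, adjusted p = 0.122) was the member closest to passing. limma called 10 probe sets, 7 higher and 3 lower, with 2741 at unadjusted p < 0.05, whereas 1 fit of all 30 arrays called 161 higher and 235 lower. Leaving out 1 array of the 2 times gave counts of 0 without 0 h replicate 1, 0 without 0 h replicate 2, 2 without 6 h replicate 1 and 0 without 6 h replicate 2.

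At 24 h Angptl4 (2.19 ± 0.12, adjusted p = 0.00222), Pdk4 (1.97) and Eci1 (1.38) were the named genes that rose in the stomach, Angptl4 from 7.13 ± 0.06 at 0 h to 9.32 ± 0.12 at 24 h. Fatty acid oxidation genes shifted upwards, where 2 rose, or 3 when adjusted over the list alone (median 0.25). The fatty acid oxidation list had camera adjusted p = 4.89e-06, and adjusted p = 0.286 with an estimated correlation. Cholesterol synthesis genes shifted downwards, where 0 fell, or 0 when adjusted over the list alone (median -0.41). The cholesterol synthesis list had camera adjusted p = 2.44e-05, and adjusted p = 0.784 with an estimated correlation, the camera p being 0.095 without 24 h replicate 1. Of the 8 parietal cell markers 0 fell, or 0 when adjusted over the list alone (median -0.48). The parietal cell list had camera adjusted p = 0.0179, and adjusted p = 0.667 with an estimated correlation, the camera p being 0.073 without 0 h replicate 1 and 0.281 without 24 h replicate 1. Replicate 1 at 24 h had the largest GAPDH 3' to 5' gap of the stomach arrays, 0.557 in log2 against 0.292 for the next. The same array carried less Gast (6.81, against 8.53 or more on the other stomach arrays), Tff2 (10.12, against 12.71 or more) and Fabp2 (8.88, against 10.93 or more), and more Krt5 (11.04, against 10.98 on 72 h replicate 2 and at most 9.58 on the others). limma called 5 probe sets, all higher, with 2589 at unadjusted p < 0.05 and a median standard error of 0.122. The counts were 0 without 0 h replicate 1, 0 without 0 h replicate 2, 2 without 24 h replicate 1 and 43 without 24 h replicate 2, the last with 7 higher and 36 lower, and 1 fit of all 30 arrays called 9 higher and 16 lower.

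At 72 h Fetub (4.34 ± 0.34, adjusted p = 0.0247) and Angptl4 (1.48) rose in the stomach. Fetub, which encodes the protease inhibitor fetuin B, went from 6.91 ± 0.59 at 0 h to 11.25 ± 0.74 at 72 h. Among the 13 macrophage markers, 0 rose, or 7 when adjusted over the list alone (median 1.02). The macrophage list had camera adjusted p = 4.95e-08, and adjusted p = 0.611 with an estimated correlation. Fatty acid oxidation genes shifted upwards here too, where 1 rose, or 3 when adjusted over the list alone (median 0.25). The fatty acid oxidation list had camera adjusted p = 5.09e-06, and adjusted p = 0.286 with an estimated correlation. Pancreatic acinar genes, of which 0 rose, or 10 when adjusted over the list alone (median 3.54), had a median signal of 13.16 on replicate 1 and 8.55 on replicate 2. The pancreatic acinar list had camera adjusted p = 2.43e-08, and adjusted p = 0.698 with an estimated correlation. For the squamous epithelium markers, 0 rose, or 0 when adjusted over the list alone (median 1.13). The squamous epithelium list had camera adjusted p = 0.00448, and adjusted p = 0.784 with an estimated correlation, the camera p being 0.749 without 0 h replicate 1 and 0.521 without 72 h replicate 2. limma called 2 probe sets, both higher, with 2346 at unadjusted p < 0.05, and the count was 0 without 0 h replicate 1, 0 without 0 h replicate 2, 321 without 72 h replicate 1 and 344 without 72 h replicate 2. Between 24 and 72 h Fetub (4.38 ± 0.34, adjusted p = 0.0361) rose, while Pdk4 (-1.22 ± 0.13, adjusted p = 0.103) and Eci1 (-1.24) lay lower without passing. limma called 1 probe set there, with 4653 at unadjusted p < 0.05 and counts of 0 without 24 h replicate 1, 49 without 24 h replicate 2, 237 without 72 h replicate 1 and 361 without 72 h replicate 2.

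In the jejunum at 1 h, Ccl20 (1.84 ± 0.22, adjusted p = 0.0446), Ddit4 (1.59), Gem (1.16), Klf2 (1.06), Txnip (1.04), Arrdc3 (0.86) and N4bp2l1 (0.74) rose. Another probe set of Klf2 differed by -0.099. Ddit4, which encodes an inhibitor of mTORC1 signalling, stood at 7.63 ± 0.17 at 0 h and 9.22 ± 0.066 at 1 h. Among the glucocorticoid targets, 1 rose, or 10 rose and 1 fell when adjusted over the list alone (median 0.71). The glucocorticoid list had camera adjusted p = 1.09e-14, and adjusted p = 0.275 with an estimated correlation. Ddit4 is also one of the 24 p53 targets. Of those 1 rose, or 5 when adjusted over the list alone (median 0.15). The p53 list had camera adjusted p = 3.87e-09, and adjusted p = 0.275 with an estimated correlation. Plk2 (1.16 ± 0.17, adjusted p = 0.107) was next closest to passing. B cell markers shifted upwards, where 0 rose, or 5 when adjusted over the list alone (median 0.28). The B cell list had camera adjusted p = 5.09e-06, and adjusted p = 0.586 with an estimated correlation. limma called 11 of 31042 probe sets, all higher, with 1467 at unadjusted p < 0.05 and a median standard error of 0.103. It called 0 with dim probe sets dropped and 0 with replicate number as a block. The count was 0 without 0 h replicate 1, 0 without 0 h replicate 2, 17 without 1 h replicate 1 and 2 without 1 h replicate 2.

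At 6 h the jejunum carried less mRNA for cell division genes: Ccnb2 (-1.46 ± 0.15, adjusted p = 0.00388), Cks2 (-1.38), Cdkn3 (-1.26) and Pclaf (-1.21) fell, Ccnb2 from 9.09 ± 0.13 at 0 h to 7.63 ± 0.073 at 6 h. Of the 31 mitosis genes 22 fell, or 30 when adjusted over the list alone (median -0.67). The mitosis list had camera adjusted p = 4.9e-22, and adjusted p = 0.286 with an estimated correlation. Of the 27 DNA replication genes 4 fell, or 8 when adjusted over the list alone (median -0.22). The DNA replication list had camera adjusted p = 0.000421, and adjusted p = 0.698 with an estimated correlation. The p53 targets Ccng1 (1.58 ± 0.21, adjusted p = 0.00874), Plk2 (1.11), Cdkn1a (0.91), Aen (0.57) and Mdm2 (0.46) rose. Over that list 6 rose, or 10 rose and 1 fell when adjusted over the list alone (median 0.17). The p53 list had camera adjusted p = 0.000134, and adjusted p = 0.306 with an estimated correlation. The glucocorticoid targets Fkbp5 (2.14 ± 0.15, adjusted p = 0.00202), Mt2A (1.67), Cebpd (1.48) and Cebpb (0.78) rose, where 4 rose, or 9 when adjusted over the list alone (median 0.51). The glucocorticoid list had camera adjusted p = 1.76e-07, and adjusted p = 0.306 with an estimated correlation. Further transcripts that rose were the BMP antagonist Grem1 (2.25 ± 0.19, adjusted p = 0.00232), the antimicrobial lectin Reg3g (2.11), Gem (2.03) and the chemokines Cxcl10 (1.69) and Ccl20 (1.65), and further ones that fell were Rab30 (-1.28), Fam13a (-1.19) and Cmss1 (-1.17). Of the NF-kB and inflammatory genes 3 rose, or 5 when adjusted over the list alone (median 0.22). The NF-kB list had camera adjusted p = 0.00422, and adjusted p = 0.716 with an estimated correlation.

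The crypt base marker Lgr5 (-0.62 ± 0.12, adjusted p = 0.0304) fell at 6 h. Of the 12 crypt base markers 2 fell, or 4 when adjusted over the list alone (median -0.28). The crypt base list had camera adjusted p = 0.0324, and adjusted p = 0.784 with an estimated correlation, the camera p being 0.0719 without 0 h replicate 2. The pore-forming tight junction gene Cldn2 (1.53 ± 0.30, adjusted p = 0.0309) rose. Of the 14 cell junction genes 3 rose, or 5 when adjusted over the list alone (median 0.32). The cell junctions list had camera adjusted p = 0.00758, and adjusted p = 0.529 with an estimated correlation. Across all probe sets the jejunum 6 h fold changes correlated at 0.284 with the difference between the jejunum 24 h replicates, for which RNA quality is a candidate explanation (below). The GAPDH gap of 6 h replicate 1 (0.381) was the largest in the jejunum after that of 24 h replicate 1. limma called 1082 probe sets at 6 h, 714 higher and 368 lower, 105 of them changed by at least 2-fold, with 6189 at unadjusted p < 0.05. The count was 18 without 0 h replicate 1, 55 without 0 h replicate 2, 26 without 6 h replicate 1 and 19 without 6 h replicate 2, and 4 of the 24 genes named as changed passed whichever of these 4 arrays was left out.

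At 24 h Timp1 (2.13 ± 0.14, adjusted p = 0.00289), Tmigd1 (2.16), Mgp (1.69), Ifitm3 (1.69) and Igfbp5 (1.65) rose in the jejunum. Timp1, an inhibitor of matrix metalloproteases, went from 7.77 ± 0.14 at 0 h to 9.90 ± 0.053 at 24 h. The matrix genes Fn1 (1.50 ± 0.15, adjusted p = 0.0145) and Postn (1.44) rose. Of the 18 fibroblast and matrix genes 2 rose, or 6 rose and 1 fell when adjusted over the list alone (median 0.26). The fibroblast and matrix list had camera adjusted p = 0.000293, and adjusted p = 0.761 with an estimated correlation. Over the matrix proteases and inhibitors, which hold Timp1, 1 rose, or 3 when adjusted over the list alone (median 0.10). The protease and inhibitor list had camera adjusted p = 0.00775, and adjusted p = 0.776 with an estimated correlation, the camera p being 0.465 without 24 h replicate 2. The p53 target Ccng1 (1.56 ± 0.21, adjusted p = 0.0301) was higher. Of that list 1 rose, or 5 when adjusted over the list alone (median 0.15). The p53 list had camera adjusted p = 0.000392, and adjusted p = 0.306 with an estimated correlation. The heat shock gene Hspb1 (1.22 ± 0.16, adjusted p = 0.0258) rose. Of its list 1 rose, or 5 rose and 1 fell when adjusted over the list alone (median 0.37). The heat shock list had camera adjusted p = 0.00627, and adjusted p = 0.583 with an estimated correlation, the camera p being 0.065 without 0 h replicate 2. Lower transcripts included the clock output gene Dbp (-1.78 ± 0.22, adjusted p = 0.0199), Fam13a (-1.37), Ddc (-1.05), Hnmt (-1.05), Blvra (-0.84) and the glutathione transferases Gsta4 (-0.98) and Gsta3 (-0.82). Smooth muscle markers shifted upwards, where 0 rose, or 2 when adjusted over the list alone (median 0.39). The smooth muscle list had camera adjusted p = 0.00201, and adjusted p = 0.784 with an estimated correlation, the camera p being 0.0502 without 0 h replicate 1 and 0.708 without 24 h replicate 1. Replicate 1 at 24 h had the largest GAPDH 3' to 5' gap of all jejunum arrays, 0.816 in log2 against 0.381 for the next, and its correlation with replicate 2 was 0.972. limma called 127 probe sets, 99 higher and 28 lower, with 4966 at unadjusted p < 0.05. The count was 1 without 0 h replicate 1, 0 without 0 h replicate 2, 830 without 24 h replicate 1 and 5133 without 24 h replicate 2, and 0 of the 16 genes named as changed passed whichever of these 4 arrays was left out.

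**Figure D3:**
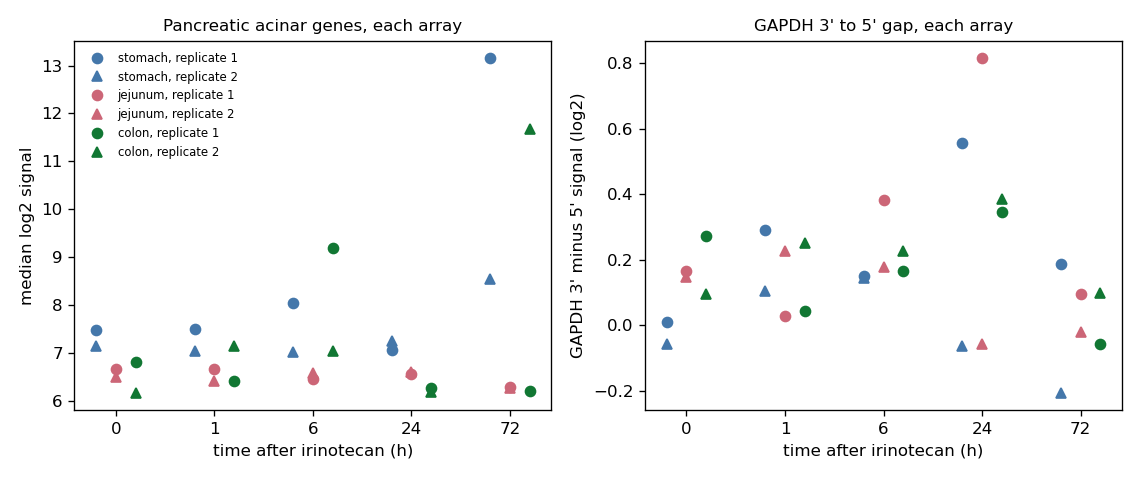
Median log2 signal of the pancreatic acinar genes and the GAPDH 3' to 5' gap on each of the 30 arrays. The pancreatic medians stand out on stomach 72 h replicate 1 (13.16), colon 72 h replicate 2 (11.68) and colon 6 h replicate 1 (9.20), and the gap on jejunum 24 h replicate 1 (0.816) and stomach 24 h replicate 1 (0.557).

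At 72 h the jejunum carried more mRNA for cell division and ribosome production: Ccna2 (1.21 ± 0.13, adjusted p = 0.000911), Kif23 (1.07), Mcm5 (0.78), Mcm7 (0.95), Ddx21 (1.23) and Ncl (1.20) rose, Ccna2 from 8.11 ± 0.061 at 0 h to 9.32 ± 0.078 at 72 h. Of the mitosis genes 25 rose, or 27 when adjusted over the list alone (median 0.53). The mitosis list had camera adjusted p = 3.24e-10, and adjusted p = 0.583 with an estimated correlation. DNA replication genes moved the same way, where 22 rose, or 23 when adjusted over the list alone (median 0.63). The DNA replication list had camera adjusted p = 3.41e-10, and adjusted p = 0.583 with an estimated correlation. All the ribosome biogenesis genes measured were higher: 19 rose, or 19 when adjusted over the list alone (median 0.77). The ribosome biogenesis list had camera adjusted p = 5.4e-10, and adjusted p = 0.306 with an estimated correlation. Of the 23 DNA repair genes 14 rose, or 15 when adjusted over the list alone (median 0.42). The DNA repair list had camera adjusted p = 2.08e-05, and adjusted p = 0.583 with an estimated correlation. The p53 target Ccng1 (1.61 ± 0.21, adjusted p = 0.00197) was higher, whereas Cdkn1a (0.11 ± 0.21, adjusted p = 0.713) and Mdm2 (0.20) did not pass. Of the endoplasmic reticulum stress genes 9 rose, or 9 when adjusted over the list alone (median 0.37). The endoplasmic reticulum stress list had camera adjusted p = 0.0215, and adjusted p = 0.784 with an estimated correlation. Asns (1.25 ± 0.14, adjusted p = 0.000903), an asparagine synthetase induced by that response, rose among them.

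Matrix transcripts also rose in the jejunum at 72 h: Fn1 (1.78 ± 0.15, adjusted p = 0.000564), Col3a1 (1.70), Col4a1 (1.42), Col6a3 (1.30), Timp1 (2.01), Plat (2.66), Mgp (2.52) and Grem1 (2.12). Of the fibroblast and matrix genes 14 rose, or 15 when adjusted over the list alone (median 0.91). The fibroblast and matrix list had camera adjusted p = 6.09e-08, and adjusted p = 0.586 with an estimated correlation. Of the 13 matrix proteases and inhibitors 6 rose, or 7 when adjusted over the list alone (median 0.88). The protease and inhibitor list had camera adjusted p = 0.00221, and adjusted p = 0.712 with an estimated correlation. Smooth muscle markers were higher beside them, Des (1.24 ± 0.25, adjusted p = 0.0107) among these, where 4 rose, or 6 when adjusted over the list alone (median 0.55). The smooth muscle list had camera adjusted p = 0.00562, and adjusted p = 0.793 with an estimated correlation. The macrophage genes Cd163 (1.19 ± 0.12, adjusted p = 0.000711), Cd14 (1.23) and Mrc1 (1.21) rose. Over that list 5 rose and 1 fell, or 9 rose and 1 fell when adjusted over the list alone (median 0.84). The macrophage list had camera adjusted p = 0.00734, and adjusted p = 0.784 with an estimated correlation. Enterocyte transcripts fell, the sugar transporters Slc2a2 (-1.12 ± 0.17, adjusted p = 0.00377) and Slc2a5 (-1.78), trehalase Treh (-1.06) and villin Vil1 (-0.60) among them. Of the 19 enterocyte markers 6 fell, or 6 when adjusted over the list alone (median -0.23). The enterocyte list had camera adjusted p = 0.00136, and adjusted p = 0.586 with an estimated correlation. Of the 17 ion and water transport genes 1 rose and 8 fell, or 1 rose and 8 fell when adjusted over the list alone (median -0.24). The ion and water transport list had camera adjusted p = 0.018, and adjusted p = 0.583 with an estimated correlation. Among them Slc12a2 (0.95 ± 0.088, adjusted p = 0.00064) was higher and Slc26a3 (-0.77 ± 0.12) and Aqp3 (-0.90 ± 0.23) were lower. Other large changes were Ly6al (4.04 ± 0.38, adjusted p = 0.00064), the goblet cell gene Spink4 (2.69), Cldn2 (2.15) and Ctsl (1.99) upwards and Dbp (-1.81), the drug efflux pump Abcb1a (-1.39), Hnmt (-1.34), Fam13a (-1.33) and Bco1 (-1.32) downwards. limma called 7405 probe sets, 3692 higher and 3713 lower, 404 of them changed by at least 2-fold (335 higher, 69 lower), with 12394 at unadjusted p < 0.05. The median fold change over all probe sets was -0.067, so small falls may hold in part a shift of whole arrays that was not rescaled. Higher calls outnumbered lower ones with dim probe sets dropped (2827 and 1444), after quantile normalization (2739 and 2475), in 1 fit of all 30 arrays (2971 and 2948) and on leaving out any 1 of the 4 arrays at 0 and 72 h. Lower calls stayed more numerous with a trend and robust variances (3592 higher, 4006 lower), with array weights (5384, 6408) and without arrays of low RNA quality (5484, 6260). The count was 2582 without 0 h replicate 1, 1692 without 0 h replicate 2, 1723 without 72 h replicate 1 and 3111 without 72 h replicate 2, and 36 of the 51 genes named as changed passed whichever of these 4 arrays was left out.

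Between 24 and 72 h the jejunum gained Mboat1 (1.84 ± 0.091, adjusted p = 0.000218), Psat1 (1.56), Tspan1 (1.26), Pno1 (1.15) and Pola1 (1.02), Pola1 being 1 of the DNA replication genes. limma called 4010 probe sets, 2723 higher and 1287 lower at 72 h, with 9710 at unadjusted p < 0.05 and a median standard error of 0.103. The count was 4363 without 24 h replicate 1, 8965 without 24 h replicate 2, 912 without 72 h replicate 1 and 1361 without 72 h replicate 2.

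In the colon at 1 h no gene passed, and Gem (1.25 ± 0.16, adjusted p = 0.156), Id2 (0.82), Depp1 (0.84) and Rhob (0.90) had the smallest p. Gem stood at 7.73 ± 0.14 at 0 h and 8.98 ± 0.044 at 1 h. Mitosis genes nevertheless shifted downwards as a list, where 0 fell, or 14 when adjusted over the list alone (median -0.37). The mitosis list had camera adjusted p = 2.85e-09, and adjusted p = 0.586 with an estimated correlation. Aurka (-0.54 ± 0.11, adjusted p = 0.26) was the member closest to passing. Of the glucocorticoid targets 0 rose, or 8 when adjusted over the list alone (median 0.43). The glucocorticoid list had camera adjusted p = 1.94e-09, and adjusted p = 0.583 with an estimated correlation. Of the immediate early genes 0 rose, or 4 when adjusted over the list alone (median 0.35). The immediate early list had camera adjusted p = 6.89e-05, and adjusted p = 0.667 with an estimated correlation. limma called 0 of 31042 probe sets at 1 h, with 4624 at unadjusted p < 0.05, a smallest adjusted p of 0.156 and a median standard error of 0.125. limma after quantile normalization called 3, limma with array weights 3, 1 limma fit of all 30 arrays 104, and limma without the arrays with transcripts of another organ 4. Leaving out 1 array of the 2 times gave 2 without 0 h replicate 1, 0 without 0 h replicate 2, 0 without 1 h replicate 1 and 0 without 1 h replicate 2.

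At 6 h cell division transcripts fell in the colon: Ccnb2 (-2.18 ± 0.19, adjusted p = 0.000775), Cdkn3 (-2.10), Cenpf (-1.88), Ube2c (-1.67), Top2a (-1.63) and Ccnb1 (-1.42), Ccnb2 from 9.52 ± 0.08 at 0 h to 7.35 ± 0.38 at 6 h. Of the 31 mitosis genes 26 fell, or 30 when adjusted over the list alone (median -1.21). The mitosis list had camera adjusted p = 6.31e-45, and adjusted p = 0.275 with an estimated correlation. Other transcripts that fell were Esrrg (-1.90 ± 0.26, adjusted p = 0.00568), Plcb1 (-1.75), Ptprd (-1.71) and Vps13b (-1.68). Another probe set of Ptprd differed by 0.061. The glucocorticoid targets Mt2A (2.41 ± 0.30, adjusted p = 0.00379), Cebpd (1.43) and Sgk1 (0.84) rose, where 3 rose, or 6 when adjusted over the list alone (median 0.27). The glucocorticoid list had camera adjusted p = 2.49e-05, and adjusted p = 0.619 with an estimated correlation. Kcnj8 (1.91 ± 0.17, adjusted p = 0.00085), Ifitm3 (1.54), Fgl2 (1.50) and Adamts1 (1.32) also rose. Of the p53 targets 0 rose, or 3 rose and 1 fell when adjusted over the list alone (median 0.18). The p53 list had camera adjusted p = 0.00288, and adjusted p = 0.583 with an estimated correlation. Ccng1 (0.78 ± 0.19, adjusted p = 0.0866) did not pass. Ins2, an insulin gene of the endocrine pancreas, lay at 9.35 and 9.78 on the colon arrays at 6 h, at 9.82 on 1 h replicate 2 and at 10.9 on 72 h replicate 2, against 6.30 and 6.13 on the other arrays at 1 and 72 h and 6.11 and 6.17 at 0 h. Pancreatic acinar genes had a median signal of 9.20 on replicate 1 and 7.03 on replicate 2, where 0 rose, or 0 when adjusted over the list alone (median 1.50). The pancreatic acinar list had camera adjusted p = 0.0464, and adjusted p = 0.865 with an estimated correlation, the camera p being 0.143 without 0 h replicate 2 and 0.488 without 6 h replicate 1. limma called 368 probe sets, 62 higher and 306 lower, 120 of them changed by at least 2-fold, with 4381 at unadjusted p < 0.05. The count was 91 without 0 h replicate 1, 92 without 0 h replicate 2, 79 without 6 h replicate 1 and 264 without 6 h replicate 2, and 9 of the 17 genes named as changed passed whichever of these 4 arrays was left out.

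At 24 h the colon carried less mRNA for cell division: Cdkn3 (-1.94 ± 0.16, adjusted p = 0.00156), Cks2 (-1.94), Knstrn (-1.75) and Ccnb2 (-1.69) were lower, Cdkn3 from 9.77 ± 0.017 at 0 h to 7.83 ± 0.0059 at 24 h. Of the mitosis genes 26 fell, or 30 when adjusted over the list alone (median -1.26). The mitosis list had camera adjusted p = 1.55e-39, and adjusted p = 0.275 with an estimated correlation. Of the DNA replication genes 3 fell, or 23 when adjusted over the list alone (median -0.47). The DNA replication list had camera adjusted p = 5.67e-13, and adjusted p = 0.586 with an estimated correlation. DNA repair genes moved the same way, where 1 fell, or 7 when adjusted over the list alone (median -0.26). The DNA repair list had camera adjusted p = 3.6e-05, and adjusted p = 0.586 with an estimated correlation. Transcripts of cholesterol synthesis fell, Acat2 (-1.16 ± 0.15, adjusted p = 0.00538), Dhcr7 (-1.04), Cyp51 (-0.90) and Fdft1 (-0.75) among them. Of the 20 measured 8 fell, or 16 when adjusted over the list alone (median -0.71). The cholesterol synthesis list had camera adjusted p = 1.29e-12, and adjusted p = 0.306 with an estimated correlation. The fatty acid oxidation gene Cpt1a (0.58 ± 0.11, adjusted p = 0.0401) rose, where 1 rose, or 9 when adjusted over the list alone (median 0.33). The fatty acid oxidation list had camera adjusted p = 0.00013, and adjusted p = 0.667 with an estimated correlation. The interferon-induced genes Isg15 (1.09 ± 0.19, adjusted p = 0.025) and Irf7 (1.02) rose. Of the 25 interferon response genes 2 rose, or 6 when adjusted over the list alone (median 0.20). The interferon response list had camera adjusted p = 0.0413, and adjusted p = 0.809 with an estimated correlation, the camera p being 0.952 without 0 h replicate 1 and 0.38 without 24 h replicate 2. Other transcripts that changed were Slc51a (1.89 ± 0.34, adjusted p = 0.0318), Ifitm3 (1.84), Hsd17b6 (1.66) and Rgs4 (1.62) upwards and Lpo (-2.43), Ccn3 (-2.05), B3gnt7 (-2.04) and Tifa (-1.63) downwards.

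The gastric transcripts Gkn2 (3.73 ± 0.76, adjusted p = 0.0489) and Gkn1 (3.49) were the highest rises in the colon at 24 h. Of the 8 gastric mucous cell markers 2 rose, or 3 rose and 1 fell when adjusted over the list alone (median 0.48). The gastric mucous cell list had camera adjusted p = 0.0182, and adjusted p = 0.583 with an estimated correlation. Replicate 1 carried Pgc at 13.67 and Atp4a at 9.41 against 8.45 and 6.92 for the higher 0 h array, while replicate 2 carried them at 6.96 and 6.65 and Gkn1 at 9.89. The 0 h arrays were unequal as well, with Pgc at 8.45 and Gkn2 at 7.70 on replicate 1 and 6.60 and 6.09 on replicate 2. Replicate 2 also carried Apoa4 at 10.31, against 8.71 for the higher 0 h array, and Fabp2 at 12.06, against 10.15. Enteric neuron and glia markers shifted upwards, where 0 rose, or 6 when adjusted over the list alone (median 0.30). The enteric neuron and glia list had camera adjusted p = 6.92e-05, and adjusted p = 0.667 with an estimated correlation. Smooth muscle markers did too, Des (0.77 ± 0.12, adjusted p = 0.0126) among them, where 2 rose, or 4 when adjusted over the list alone (median 0.19). The smooth muscle list had camera adjusted p = 0.00463, and adjusted p = 0.784 with an estimated correlation, the camera p being 0.787 without 24 h replicate 1. limma called 355 probe sets, 90 higher and 265 lower, 129 of them changed by at least 2-fold, with 5196 at unadjusted p < 0.05. The count was 105 without 0 h replicate 1, 0 without 0 h replicate 2, 205 without 24 h replicate 1 and 595 without 24 h replicate 2, and 0 of the 22 genes named as changed passed whichever of these 4 arrays was left out.

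At 72 h A2m (2.62 ± 0.27, adjusted p = 0.00708), F3 (2.53), Mgp (2.45), Adamts1 (2.00), Fcgr2b (1.91) and Steap4 (1.90) rose in the colon. A2m, a broad protease inhibitor, went from 6.50 ± 0.016 at 0 h to 9.12 ± 0.11 at 72 h. The macrophage gene Cd163 (1.85 ± 0.30, adjusted p = 0.0211) rose. Of the 13 macrophage markers 2 rose, or 10 when adjusted over the list alone (median 1.18). The macrophage list had camera adjusted p = 3.53e-07, and adjusted p = 0.667 with an estimated correlation. The matrix genes Mmp2 (1.50 ± 0.24, adjusted p = 0.0205), Timp1 (1.25), Plau (0.99) and Col4a1 (1.05) rose. Of the matrix proteases and inhibitors 3 rose, or 10 when adjusted over the list alone (median 0.62). The protease and inhibitor list had camera adjusted p = 1.81e-07, and adjusted p = 0.583 with an estimated correlation. Of the fibroblast and matrix genes 3 rose, or 15 when adjusted over the list alone (median 0.58). The fibroblast and matrix list had camera adjusted p = 3.8e-11, and adjusted p = 0.583 with an estimated correlation. The NF-kB and inflammatory genes shifted upwards, where 1 rose, or 12 when adjusted over the list alone (median 0.50). The NF-kB list had camera adjusted p = 1.69e-07, and adjusted p = 0.583 with an estimated correlation. Isg15 (1.35 ± 0.19, adjusted p = 0.0146) and Ifit2 (1.34) rose. Of the interferon response genes 4 rose, or 6 when adjusted over the list alone (median 0.13). The interferon response list had camera adjusted p = 0.0243, and adjusted p = 0.784 with an estimated correlation, the camera p being 0.785 without 0 h replicate 1 and 0.462 without 72 h replicate 2. The sodium-proton exchanger Slc9a3 (-0.96 ± 0.12, adjusted p = 0.0131), the chloride channel Cftr (-1.01) and the bicarbonate transporter Slc4a4 (-1.14) fell, and the aquaporin Aqp7 (1.32) rose. Of the ion and water transport genes 1 rose and 5 fell, or 2 rose and 5 fell when adjusted over the list alone (median -0.23). The ion and water transport list had camera adjusted p = 0.0307, and adjusted p = 0.784 with an estimated correlation, the camera p being 0.466 without 72 h replicate 1. Further genes that fell were Prlr (-1.42 ± 0.24, adjusted p = 0.0253), Tnfsf10 (-1.30), Kat6b (-1.21) and Slc25a10 (-1.15).

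Cd36 (2.30 ± 0.45, adjusted p = 0.0396) and Lpl (2.26) also rose in the colon at 72 h, neither of them on the adipocyte list. Of the 8 adipocyte markers 0 rose, or 5 when adjusted over the list alone (median 1.24). The adipocyte list had camera adjusted p = 0.00363, and adjusted p = 0.698 with an estimated correlation, the camera p being 0.0661 without 72 h replicate 2. Pancreatic acinar genes had a median signal of 11.68 on replicate 2 and 6.19 on replicate 1, where 0 rose, or 0 when adjusted over the list alone (median 2.64). The pancreatic acinar list had camera adjusted p = 0.000311, and adjusted p = 0.784 with an estimated correlation, the camera p being 0.728 without 72 h replicate 2. The gastric genes Pgc, Gkn2 and Tff1 lay at 9.76, 8.51 and 8.73 on colon 72 h replicate 1 against 6.48, 5.98 and 6.79 on replicate 2. Across all probe sets the colon 72 h fold changes correlated at -0.402 with the difference between the jejunum 24 h replicates. RNA quality is a candidate explanation of that difference, as described below. limma called 411 probe sets, 277 higher and 134 lower, 128 of them changed by at least 2-fold, with 5337 at unadjusted p < 0.05. The count was 3 without 0 h replicate 1, 0 without 0 h replicate 2, 309 without 72 h replicate 1 and 787 without 72 h replicate 2, and 0 of the 24 genes named as changed passed whichever of these 4 arrays was left out.

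Between 24 and 72 h cell division transcripts rose in the colon, Cks2 (1.88 ± 0.16, adjusted p = 0.0017), Cdkn3 (1.82), Ttk (1.62) and Depdc1 (1.27) among the 5 smallest p together with Gstt3 (1.26). limma called 2088 probe sets, 1365 higher and 723 lower at 72 h, with 8189 at unadjusted p < 0.05, and quantile normalization moved the split to 1121 and 1029. The count was 293 without 24 h replicate 1, 3363 without 24 h replicate 2, 539 without 72 h replicate 1 and 1886 without 72 h replicate 2.

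Each gene is given below for the pair of tissues that differed most, and other pairs can pass too. Mipol1, for example, also differed by 1.02 (jejunum minus stomach, limma adjusted p = 0.021). Ptf1a at 1 h (-0.99) and Mipol1 (-1.27) and Ppp2r2b (-1.47) at 6 h lay lower than at 0 h in the stomach. At 24 h Knstrn (-1.18 on this probe set) and Egf (-1.62) lay lower in the colon. For the other genes with a positive difference, it came mainly from a rise in the first tissue named. Ptf1a differed at 1 h between colon and stomach (colon minus stomach 1.11 ± 0.16, adjusted p = 0.0268). At 6 h Slc25a36 and Dyrk2 differed between jejunum and colon (jejunum minus colon 1.79 ± 0.24, adjusted p = 0.00727 and 1.30 ± 0.18, adjusted p = 0.00727), Ppp2r2b and Selenoi between jejunum and stomach (jejunum minus stomach 1.66 ± 0.22, adjusted p = 0.0038 and 1.15 ± 0.15, adjusted p = 0.0038), and Mipol1 between colon and stomach (colon minus stomach 1.19 ± 0.16, adjusted p = 0.0152). At 24 h Slc25a36, Knstrn and Egf differed between jejunum and colon (jejunum minus colon 2.05 ± 0.24, adjusted p = 0.00235, 1.05 ± 0.14, adjusted p = 0.00335 and 1.59 ± 0.25, adjusted p = 0.0136), and Gkn1 and Coch between colon and stomach (colon minus stomach 3.58 ± 0.55, adjusted p = 0.0145 and 1.55 ± 0.22, adjusted p = 0.0139). At 72 h Fetub and Ncoa7 differed between jejunum and stomach (jejunum minus stomach -4.65 ± 0.34, adjusted p = 7.65e-07 and 1.39 ± 0.15, adjusted p = 0.00013), Ly6al and Dusp23 between jejunum and colon (jejunum minus colon 4.15 ± 0.41, adjusted p = 0.000121 and -1.08 ± 0.13, adjusted p = 0.000583), and Cyp2f4 between colon and stomach (colon minus stomach -1.01 ± 0.11, adjusted p = 0.00048). The fall in mitosis genes at 6 h differed between colon and stomach (median difference -0.64, camera adjusted p = 2.13e-24, adjusted p = 0.876 with an estimated correlation) and between jejunum and colon (0.55, camera adjusted p = 8.61e-07, adjusted p = 0.955 with an estimated correlation). At 72 h mitosis genes differed between jejunum and colon (0.58, camera adjusted p = 3.65e-08, adjusted p = 0.93 with an estimated correlation) and ribosome biogenesis genes between jejunum and stomach (0.59, camera adjusted p = 3.65e-08, adjusted p = 0.93 with an estimated correlation). F tests over the tissues called 1, 78, 71 and 708 of 31042 probe sets at 1, 6, 24 and 72 h, with 2815, 4256, 4088 and 6076 at unadjusted p < 0.05. Leaving out 1 of the 12 arrays at 0 h and the treated time gave at 1 h 0 (stomach 0 h replicate 1) to 3 (colon 0 h replicate 1), at 6 h 4 (jejunum 6 h replicate 2) to 178 (colon 6 h replicate 2), at 24 h 5 (colon 0 h replicate 2) to 199 (stomach 24 h replicate 2) and at 72 h 131 (jejunum 0 h replicate 2) to 1535 (stomach 72 h replicate 1).

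Of the probe sets called at 6 h some were shared by jejunum and colon: 90 probe sets were lower in both, against 3.63 expected from independent lists, 22 were higher in both against 1.43, and 3 moved in opposite directions, with Ccnb2 and Cdkn3 lower in both. Over all 31042 probe sets these 2 responses correlated at only 0.145 and 47.2% had the same sign, while stomach and colon at 6 h, with 1 probe set higher and 2 lower in both, correlated at 0.498 with 66% of the same sign. At 72 h 161 were higher in both against 32.9 expected, 38 lower in both against 16 and 5 opposite, with Mgp and Timp1 higher in both, and over all probe sets the correlation was 0.426 with 62.5% of the same sign. The tissues of a time came from the same 6 rats, at 0 h too, so these lists are not independent, which the expected counts assume. Within the colon 94 probe sets were lower at both 6 and 24 h, and within the jejunum 387 were higher at both 6 and 72 h while 133 moved in opposite directions. Comparisons within a tissue share their 0 h arrays. In simulations of 6 and 72 h without any effect this gave correlations across genes of 0.501 in the colon and 0.499 in the jejunum. A shared control of equal size fixes them there. They thus cannot weigh the observed correlations, 0.608 in the colon (6 and 24 h) and 0.291 in the jejunum (6 and 72 h). The simulations gave 0 shared calls in either tissue, but their noise was independent between probe sets, unlike that of the arrays. Independent lists would share 2.61 lower calls in the colon pair and 84.9 higher calls in the jejunum pair.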

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

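The tests of tissue differences and the correlation of fold changes with gene length were fixed before their results were seen, and the tests of genes over 300 kb, of RNA quality, of expression level, of mislabelling, of differing pools and of pancreatic and gastric tissue were chosen afterwards.

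The response differed between tissues, by a test of the difference itself, for 1 probe set at 1 h, 78 at 6 h, 71 at 24 h and 708 at 72 h. At 1 h the pancreatic transcription factor gene Ptf1a differed by 1.11 (colon minus stomach). At 6 h Slc25a36 differed by 1.79 (jejunum minus colon) and Dyrk2 by 1.30 (jejunum minus colon). Ppp2r2b differed by 1.66 (jejunum minus stomach) and Selenoi by 1.15 (jejunum minus stomach), and Mipol1 by 1.19 (colon minus stomach). At 24 h Slc25a36 differed by 2.05 (jejunum minus colon), Knstrn by 1.05 (jejunum minus colon) and Egf by 1.59 (jejunum minus colon), while Coch differed by 1.55 (colon minus stomach) and Gkn1 by 3.58 (colon minus stomach). At 72 h Fetub differed by -4.65 (jejunum minus stomach) and Ncoa7 by 1.39 (jejunum minus stomach). Ly6al differed by 4.15 (jejunum minus colon), Dusp23 by -1.08 (jejunum minus colon) and Cyp2f4 by -1.01 (colon minus stomach). A difference does not say which tissue moved: Ptf1a (-0.99), Ppp2r2b (-1.47) and Mipol1 (-1.27) lay lower in the stomach, and Knstrn and Egf (-1.62) in the colon. No explanation was tested for the genes of this paragraph except Gkn1.

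The jejunum arrays at 24 h lay apart, with a correlation of 0.972 between replicates and GAPDH gaps that differed by 0.873 in log2. The closest jejunum array of another time correlated at 0.988, under the 0.992 of the least alike replicates of the other jejunum groups. Yet each 24 h array was closer to an array of another time than to its replicate. Replicate 1 correlated with 6 h replicate 1 at 0.985, and replicate 2 with 1 h replicate 1 at 0.988. The large GAPDH gap of replicate 1 may lower its correlations whatever its time, so this test cannot decide whether a sample was mislabelled. RNA quality is a candidate explanation: over 12 replicate pairs of other times, the difference in GAPDH gap went with the pair's likeness to the jejunum 24 h difference (Pearson r = 0.801, permutation p = 0.0021, Spearman rho = 0.832, permutation p = 0.0014, and r = 0.841 without stomach 72 h and colon 1 h). Pools of rats that responded differently stay open: the colon 24 h pair, with gaps only -0.0388 apart, correlated with the jejunum difference at 0.358, and the stomach 24 h pair, with gaps 0.619 apart, at 0.503, but the undosed colon 0 h pair did so at 0.362. Fold changes against 0 h correlated with the jejunum 24 h difference at -0.402 in the colon at 72 h. In the jejunum they did so at 0.323 at 24 h, which shares those arrays, and 0.284 at 6 h. The other responses lay between -0.209 and 0.146. These likenesses are correlations across genes, which are not independent replicates, and pairs of the same time hold RNA of the same 6 rats.

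Transcripts of the pancreas and of the stomach stood unequally on the arrays of several groups, and pancreatic tissue in the pool may be the source on stomach 72 h replicate 1, colon 6 h replicate 1 and colon 72 h replicate 2, where at least 86.7% of 15 acinar genes lay over 1 log2 above the 0 h arrays. These arrays were picked for the high median of the same genes, so that share was nearly fixed in advance and is no separate support. A response of the acinar genes to irinotecan is argued against in the colon, where list medians within a group lay at least 2.17 log2 apart, but stays open in the stomach, where replicate 2 at 72 h was also 1.08 log2 above the 0 h arrays. Ins2 stood at 10.9 on colon 72 h replicate 2 and 8.94 on stomach 72 h replicate 1, with 6.13 and 6.38 on the other replicates, but also at 9.82 on colon 1 h replicate 2 (6.30 on replicate 1) and at 9.35 and 9.78 on both colon 6 h arrays, and its source stays open. Stomach tissue may have entered colon 24 h replicate 1, where Atp4a, Atp4b, Pgc and Cblif of parietal and chief cells rose at least 2.34 log2 over the 0 h arrays, of which replicate 1 itself had more Pgc than replicate 2 (8.45 against 6.60). A rule on Pgc had marked colon 24 h replicate 1, so its Pgc is no separate support, and these genes were chosen after the arrays were seen. Tff2, at 10.12 to 13.65 on the stomach arrays, was not part of that test. It stood at only 6.34 on colon 24 h replicate 1, against 6.18 for the higher 0 h array. On colon 24 h replicate 2 Atp4a, Atp4b, Pgc and Cblif rose at most 0.037 log2, which argues against tissue with parietal and chief cells only. Gkn1, Gkn2 and Tff1 lay 2.67, 2.14 and 1.85 log2 above the 0 h arrays there and Apoa4 stood at 10.31, and what raised them stays open. The source of Pgc (9.76) and Gkn2 (8.51) on colon 72 h replicate 1 stays open too and was not tested.

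Long genes lay lower at 6 h in every tissue, which may reflect slower transcription under a topoisomerase I inhibitor. The planned correlation with gene length in stomach, jejunum and colon was -0.0595, -0.0483 and -0.181 at 1 h, -0.154, 0.094 and -0.224 at 6 h and -0.154, 0.0232 and -0.119 at 72 h, against -0.178 to 0.226 between replicates. Over all named genes, the 428 longer than 300 kb differed from the rest by -0.134, -0.109 and -0.119 in stomach, jejunum and colon against -0.0288 to 0.132 between replicates, and restricting to genes at or above the median signal after that gave -0.365, -0.201 and -0.470 against -0.0584 to 0.18. RNA quality is argued against by the 10 replicate pairs whose GAPDH gaps differed by over 0.1. In the median of these, the array with the larger gap had long genes higher (0.0371, from -0.0269 to 0.159). The colon 24 h pair, with gaps only -0.0388 apart, was not among them. Its replicate 2, with the larger gap, had long genes lower (0.18, replicate 1 minus replicate 2). The level of expression is argued against too, since the lowest median of 10000 matched sets was -0.0734 in the jejunum against -0.185 for its long genes. In any tissue 0 of the sets lay as low. Transcription and chance cannot be told apart because the differences over all genes are no larger in jejunum and colon, and barely larger in the stomach, than the largest between replicates, whose order is arbitrary, and because the restricted test was chosen on the same arrays.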

How the results depend on the processing

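Array weights, leaving out arrays with transcripts of another organ and leaving out arrays of low RNA quality were chosen after the data had been seen. The rule for another organ's transcripts kept colon 72 h replicate 1 (Pgc 9.76, Gkn2 8.51) and colon 24 h replicate 2 (Gkn1 9.89). It also kept stomach 72 h replicate 2, whose acinar median lay 1.08 log2 above the 0 h arrays. Counts under that setting therefore still rest on arrays that carried some such transcripts. The counts printed here are those that moved by over 1.5 times or crossed 0, and the cause was not tested except where fewer probe sets or arrays entered a fit. Probe sets dropped for a mean under the median left fewer to test and gave jejunum 0 (1 h), 4271 (72 h), colon 257 (72 h). Quantile normalization gave stomach 3 (1 h), 3 (24 h), 0 (72 against 24 h), colon 3 (1 h), tissue differences 2 (1 h), 38 (6 h). limma with a trend and robust variances gave stomach 8 (1 h), 27 (6 h), 7 (72 h), 0 (72 against 24 h), jejunum 4 (1 h). 1 fit of all 30 arrays gave stomach 77 (1 h), 396 (6 h), 25 (24 h), 118 (72 h), 164 (72 against 24 h), jejunum 69 (24 h), colon 104 (1 h), 737 (6 h), 897 (24 h), 787 (72 h), 3568 (72 against 24 h). Array weights gave stomach 33 (1 h), 141 (6 h), 0 (72 against 24 h), jejunum 42 (1 h), 4984 (6 h), 12 (24 h), 11792 (72 h), 1748 (72 against 24 h), colon 3 (1 h), 661 (6 h), 624 (72 h), 920 (72 against 24 h), tissue differences 28 (1 h), 1911 (6 h), 29 (24 h), 2297 (72 h). Without the arrays with transcripts of another organ the counts were stomach 56 (6 h), 321 (72 h), 237 (72 against 24 h), colon 4 (1 h), 166 (6 h), 616 (24 h), 1755 (72 h), 1113 (72 against 24 h), tissue differences 5 (1 h), 148 (24 h), 2326 (72 h). Without those of low RNA quality they were stomach 27 (6 h), 2 (24 h), 0 (72 h), 0 (72 against 24 h), jejunum 66 (1 h), 4228 (6 h), 830 (24 h), 11744 (72 h), tissue differences 2 (1 h), 244 (6 h), 1330 (72 h). For lists, 53, 50 and 54 tests passed camera in stomach, jejunum and colon at the preset correlation, and 0, 0 and 0 with the estimated correlation. The rotation test fry, which asks whether a list's own genes move 1 way, gave mitosis adjusted p of 0.0058 in the colon at 6 h, 0.00959 and 0.0125 in the jejunum at 6 and 72 h, and 0.25 in the stomach at 6 h.

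Each array of the compared groups was left out in turn, and for lists each array of the tissue, which assumes that the lone array of its group varies like the other groups. The counts ran, in the order 1, 6, 24, 72 h and 72 against 24 h, over 0 to 0, 0 to 2, 0 to 43, 0 to 344 and 0 to 361 in the stomach, 0 to 17, 18 to 55, 0 to 5133, 1692 to 3111 and 912 to 8965 in the jejunum, and 0 to 2, 79 to 264, 0 to 595, 0 to 787 and 293 to 3363 in the colon. Arrays of other times, which enter the same fits, were not left out in turn for these counts, and some counts then lie outside the ranges: without jejunum 24 h replicate 1 those of the jejunum at 1, 6 and 72 h (66, 4228 and 11744), and without stomach 24 h replicate 1 or 72 h replicate 1 those of the stomach at 1 h (5 and 6) and 6 h (27 and 56). Tissue differences ran over 0 to 3, 4 to 178, 5 to 199 and 131 to 1535, and lists past camera over 49 to 57, 48 to 56 and 48 to 64.

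Of the named fold changes under these alternatives, 1795 of 2373 kept their direction and their side of the threshold, 532 no longer passed, 370 of them on leaving out 1 array of the compared groups, 37 newly passed and 9 changed sign. The other settings refit the same probe set, so the pooled count says little about other probe sets of a gene. On those only 31 of 74 values kept direction and side, 33 no longer passed, 2 newly passed and 8 changed sign. The values that changed sign were, on another probe set, Cdkn1a (-0.0087) and Fos (-0.092) in the stomach at 1 h, Slc8a1 (0.12) in the stomach at 6 h, Klf2 (-0.099) in the jejunum at 1 h, Ptprd (0.061) in the colon at 6 h, and Bcl2l11 (-0.11 and -0.12) and Xiap (1.17) in the jejunum at 72 h, and after quantile normalization Cdkn1a (-0.040) in the jejunum at 72 h. The lowest signal of any probe set was 3.53, but this is not the background of other probe sets. The stomach transcripts Gkn1 and Atp4a read 5.88 to 6.26 and 6.66 to 7.12 in the jejunum. A fall of a gene near background is not detectable on these arrays.

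With replicate number as a block the counts were stomach 9 (1 h), 21 (6 h), 14 (72 h), 3 (72 against 24 h), jejunum 0 (1 h), 604 (6 h), 27 (24 h), colon 247 (72 h), tissue differences 0 (1 h), no other count moved by over 1.5 times, and the split in the jejunum at 72 h was 3098 higher and 2675 lower. The numbers do not pair samples in the labels: differences between replicates correlated over 0.1 in 5 of 15 pairs of tissues at the same time (-0.215 to 0.503) and in 11 of 30 pairs of times in the same tissue (-0.582 to 0.434). Every pair of tissues at 24 h was among those 5 (0.503, 0.319 and 0.358), so equal numbers may hold the same rats at 24 h, which was not tested.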

Other observations

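The test of the circadian clock genes was fixed before its result was seen.

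Genes that handle irinotecan and its metabolites passed camera as a list in neither jejunum nor colon at any time, but single ones changed. The list's Ugt1a genes (Ugt1a1, Ugt1a6 and Ugt1a7c) were not measured, nor were Ces2e, Abcb1b and Cyp3a62, so the list result does not cover them. In the jejunum at 72 h Abcb1a (-1.39 ± 0.16), Ces1e (-1.02 ± 0.13) and Slco1a4 (-0.31 ± 0.093) fell and Abcc1 (0.46 ± 0.091) rose, 4 of 10 measured, and in the colon Ces1e (-0.96 ± 0.11) fell. Of all 14217 named genes 4481 had a probe set called in the jejunum at 72 h. Calls of a few single genes there, of this list or of the apoptosis regulators below, thus do not set a list apart. Camera passed the list at the preset correlation in the stomach at 72 h, where 0 rose, or 0 when adjusted over the list alone (median 0.48, camera adjusted p = 0.00288, adjusted p = 0.586 with an estimated correlation), with p of 0.518 without 72 h replicate 1. Regulators of apoptosis passed camera in no comparison (smallest adjusted p 0.0888 in the stomach at 6 h): in the jejunum at 6 h Mcl1 (0.67 ± 0.11) rose, and at 72 h Bik (0.63 ± 0.096), Mcl1 (0.42 ± 0.11) and Bcl2l11 (0.28 ± 0.073) rose while Bak1 (-0.59 ± 0.16), Xiap (-0.59 ± 0.17) and Cflar (-0.38 ± 0.11) fell. Other probe sets of Bcl2l11 (-0.11 and -0.12) and Xiap (1.17) went the other way. Heat shock genes rose in the jejunum at 72 h, Hspb1 (1.22 ± 0.16), Bag3 (0.70 ± 0.14) and Hspa1a (0.69 ± 0.16) among them, where 6 rose, or 8 when adjusted over the list alone (median 0.57, camera adjusted p = 0.00161, adjusted p = 0.583 with an estimated correlation). On the list named colonocyte markers, Slc51a (-0.73 ± 0.10), Car4 (-0.92 ± 0.18) and Aqp8 (-0.70 ± 0.15) fell in the jejunum at 72 h, where 5 fell, or 5 when adjusted over the list alone (median -0.26, camera adjusted p = 0.00259, adjusted p = 0.583 with an estimated correlation). Aqp8 lay low in the jejunum, at 6.82 to 7.7, against 6.29 to 7.84 in the stomach and 9.67 to 12.18 in the colon.

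Rats killed at different hours of the day might differ in clock genes. The larger of the 24 and 72 h median absolute log2 fold changes of 16 clock genes was 1.1, 1.71 and 1.38 times that at 6 h in stomach, jejunum and colon, and 5 of 16 genes moved the same way in every tissue at 6 h. In the jejunum the median was 0.23 at 6 h, 0.393 at 24 h and 0.304 at 72 h, and in the colon 0.23, 0.293 and 0.317. A time-of-day effect that returns at 24 and 72 h would not alone give the later changes there. The ratio takes the larger of 2 later times, so noise raises it, and a later response of the clock genes would raise it too. A time-of-day part in the changes at 6 h therefore cannot be excluded, and the hour of killing is not given in the sources used here.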
